A study of Arabidopsis thaliana with 6 samples.

How the data were processed

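RNA immunoprecipitation followed by sequencing (RIP-seq) was analysed in whole Arabidopsis thaliana Col-0 seedlings at 14 d of age, grown at 22 °C under 16 h of light and 8 h of darkness on medium with 1% sucrose and crosslinked with 0.5% formaldehyde, per the labels' protocols. RNA bound to protein was recovered with an anti-Flag antibody. The 6 libraries formed 4 groups taken from the labels: ASI1 RIP (n = 2), ASI1 input (n = 1), WT RIP (n = 2) and WT input (n = 1). Input libraries come from RNA before precipitation. That the ASI1 line carries Flag-tagged ASI1 and that WT is the untagged background control was inferred from the antibody and the group names. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between the RIP replicates, which may be technical. Each input is a single library, so its spread was not measured. Tests and standard errors of RIP over input assume that inputs vary like the RIP libraries.

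The authors deposited 1 table per genotype with expected counts (estimated read counts per gene, which need not be whole) for the input and both RIP libraries, per the file headers. The same deposited tables give CPM, each count scaled by the listed total of its library; these deposited CPM were recomputed from the counts to check the library totals. Each table also holds the authors' log2 fold change of RIP over input and mean log2 CPM per gene. The authors' p-value and FDR per gene come from their own edgeR comparison, per the file headers. STAR 2.6.0c, Salmon 0.10.2 and edgeR were used upstream, per the submitters' processing notes; their roles, the genome build and whether counting used strand are not given in the sources used here. Per library, 96.4% to 98.8% of the values were whole multiples of a step of 1.03 to 1.05 counts, within 0.02 of a whole number. A gene was listed only if at least 2 of the 3 libraries of its table had a value above 0.

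The ASI1 table listed 4020 genes and the WT table listed 4654, with 2323 in both. All gene identifiers (100%) matched the TAIR10.1 annotation, from which symbols, biotypes, coordinates, exon numbers and introns were taken; these coordinates are those of TAIR10.1. No gene of the chloroplast or mitochondrial genome, no tRNA and no miRNA was listed (0 genes of each). Listed genes outside the 4 ribosomal RNA (rRNA) genes were expressed as CPM of the non-rRNA counts of a library, called CPM outside rRNA. A gene was called covered in a library with at least 20 counts.

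Expected counts were rounded to whole numbers and fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest, quasi-likelihood) in R 4.3.3, with limma 3.58.1 underneath. All 6 libraries were fitted together over the 2323 shared genes, with trimmed mean of M-values (TMM) scaling on the listed totals and filterByExpr, which kept 2312 genes. The contrasts were ASI1 RIP over input, WT RIP over input, and the difference of these enrichments (ASI1 minus WT). A gene was called with a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. The comparison of ASI1 RIP with WT RIP without the inputs was added after the values were seen. With 4 groups and 6 libraries the fit has 2 residual degrees of freedom, and the common dispersion was 2.19 (biological coefficient of variation 1.48).

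Gene lists were tested with camera at its preset correlation of 0.01 where at least 3 members were tested (12 lists in 3 contrasts, 36 tests, adjusted together), and again with an estimated correlation and with fry, which tests a list against no change. With an estimated correlation camera rests on the 2 residual degrees of freedom of the fit. Hardly any list could pass that test, so a call lost there decides little. The lists fixed in advance were known ASI1 targets, the ASI1-AIPP1-EDM2 complex and its partners, polyadenylation factors, DNA methylation and heterochromatin factors, nuclear photosynthesis genes, heat shock genes, rapid stress response genes, reference genes, root markers, seed storage genes, vascular and guard cell markers, ribosomal protein genes, disease resistance genes, histones, pentatricopeptide genes, transposase genes, pseudogenes, and rRNA, snRNA, snoRNA, lncRNA and other ncRNA genes. An extensin and proline-rich list and a splicing factor list were added after the values were seen and were adjusted apart from the fixed lists, over 6 tests. Spearman's rho between the log2 fold change and gene length, exon number and longest intron was computed across 2281 protein-coding genes with 100000 permutations (two-sided), as 9 relations adjusted together. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for tables, permutations and plots.

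The groups, contrasts, thresholds, fixed lists, the rule for named genes and the alternatives not marked as added were chosen before the data were examined. The rule named all members of the known targets and of the complex, the called genes with the largest folds (10 higher and 5 lower per comparison), the 10 called ASI1 genes with the largest ASI1 minus WT difference, and up to 4 members of each other list with the smallest p in the authors' deposited ASI1 table. Genes outside the rule are said to have been chosen after their values were seen.

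The fit was tested on simulated counts with 100 raised and 100 lowered genes. At the dispersion of these libraries, 2.19, it called 0 of 100 genes raised 64-fold in the ASI1 RIP, in the contrast of ASI1 RIP over input (2142 genes). At a dispersion of 0.1 it called 100 of 100 in the same contrast (2287 genes), with 5 false calls. The depth ranged from 119916 to 6383274 listed counts per library, of which 23304 to 448561 lay outside rRNA genes. A count of 0 allows up to 3 counts, which corresponds to 129 CPM outside rRNA in WT RIP replicate 1 and 6.69 in ASI1 RIP replicate 1. Ratios carry 95% exact binomial intervals and shares of counts 95% Wilson intervals. These intervals and floors cover counting error only, since reads from PCR are not independent molecules.

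Alternatives were DESeq2 1.42.0 with its size factors, no filter on low counts, each RIP replicate left out in turn, a replicate block, an FDR of 0.01, other fold minimums (none, or a log2 fold of at least 2), genes at or above the median log CPM, folds centred on their median, the Benjamini-Hochberg adjustment of the authors' deposited p-values, and intron minimums of 500 and 2000 in place of 1000 bp. Added after the values were seen were scaling to the non-rRNA counts, a fit without the rRNA genes, a quasi-likelihood spread with no abundance trend, each table fitted alone, estimated correlations and fry. Leaving out organelle genes changed nothing, as none was listed. Fisher's exact test of called genes in intron classes could not be computed with 0 genes called higher, so camera on those classes took its place.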

Results

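RIP-seq of the ASI1 protein was analysed in Arabidopsis seedlings, with 2 immunoprecipitated libraries and 1 input library from the ASI1 line and the same set from wild type (WT). ASI1 is an RNA-binding protein with a bromo-adjacent homology domain that acts with EDM2 and AIPP1 on genes carrying heterochromatin in an intron, where it favours transcripts that reach the distal polyadenylation site. The libraries ask which RNAs ASI1 binds, with WT as the background of the precipitation. The ASI1 input held 4461715 listed counts, and the ASI1 RIP libraries held 2566368 and 1804637. The WT input held 6383274 counts, against 119916 and 525126 in the WT RIP libraries.

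Ribosomal RNA took most counts in every library, and less in the RIP libraries than in the inputs. The 18S rRNA gene AT3G41768 on chromosome 3 (14197677 to 14199484) held 99.3% of the counts of the ASI1 input and 98.9% of the WT input. In the RIP libraries its share was 79.3% and 76.7% in ASI1 and 77.3% and 76.6% in WT. The short rRNA genes AT2G01020 and AT3G41979, which carried nearly equal counts in each library, together held 0.139% of the ASI1 input and 3.21% and 3.17% of its RIP libraries, and in WT 0.0612% of the input and 3.08% and 3.59% of the RIP libraries. All other genes held 0.534% of the ASI1 input counts (95% interval 0.527 to 0.540) and 0.966% of the WT input counts (0.958 to 0.973), against 17.5%, 20.1%, 19.4% and 19.7% in the RIP libraries. The rRNA genes are near-identical repeats, so how their reads were divided between copies is uncertain.

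**Figure D1:**
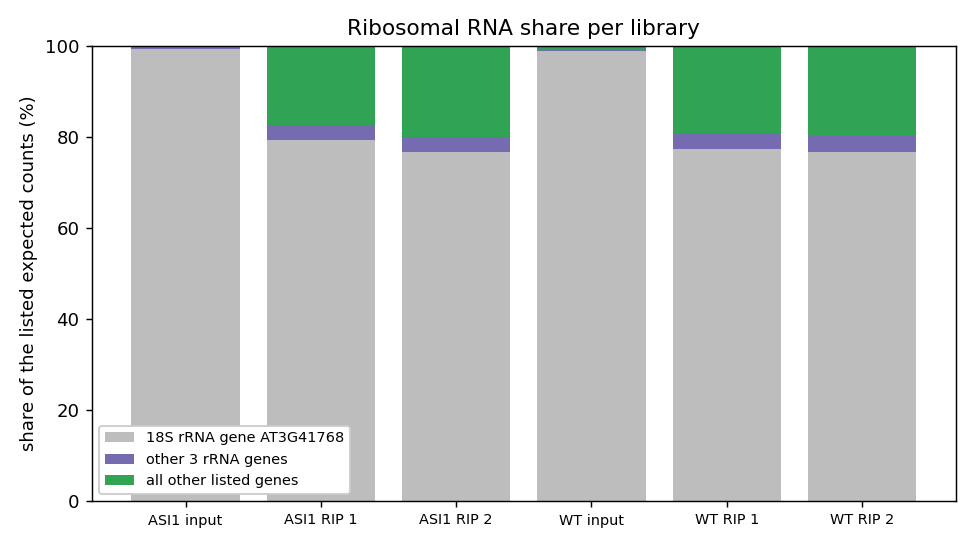
Stacked bars give the share of listed expected counts (%, y axis) per library (x axis) for the 18S rRNA gene AT3G41768, the other 3 rRNA genes and all other listed genes. Genes outside rRNA took 0.534% and 0.966% of the inputs and 17.5% to 20.1% of the 4 RIP libraries.

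Outside rRNA, the ASI1 RIP libraries covered many more genes than the WT RIP libraries, and replicates shared part of the genes they covered. The ASI1 input held 23810.4 non-rRNA counts against 448561 and 362058 in its RIP libraries, and the WT input 61644 against 23304 and 103549, so counts given for single genes compare libraries only in relation to these totals. At least 20 counts were reached by 2857 and 2416 genes in the ASI1 RIP libraries, by 183 and 867 in the WT RIP libraries, by 142 in the ASI1 input and by 460 in the WT input. Covered genes had a median of 99.3 and 99.2 counts in the ASI1 RIP libraries and 87.3 and 82.9 in the WT RIP libraries, although the non-rRNA counts of these libraries ranged from 23304 to 448561. Both ASI1 RIP libraries covered 1436 genes and both WT RIP libraries 61. Spearman's rho between the RIP replicates was -0.0142 across 4016 genes in ASI1 and 0.0993 across 4650 in WT, values that are lowered because the tables hold only genes above 0 in at least 2 of 3 libraries. Over genes above 0 in both RIP replicates rho was 0.251 in ASI1 (2096 genes) and 0.333 in WT (2318 genes). The inputs of the 2 genotypes correlated at 0.595 across 2319 genes. Genes are not independent replicates in these correlations.

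**Figure D2:**
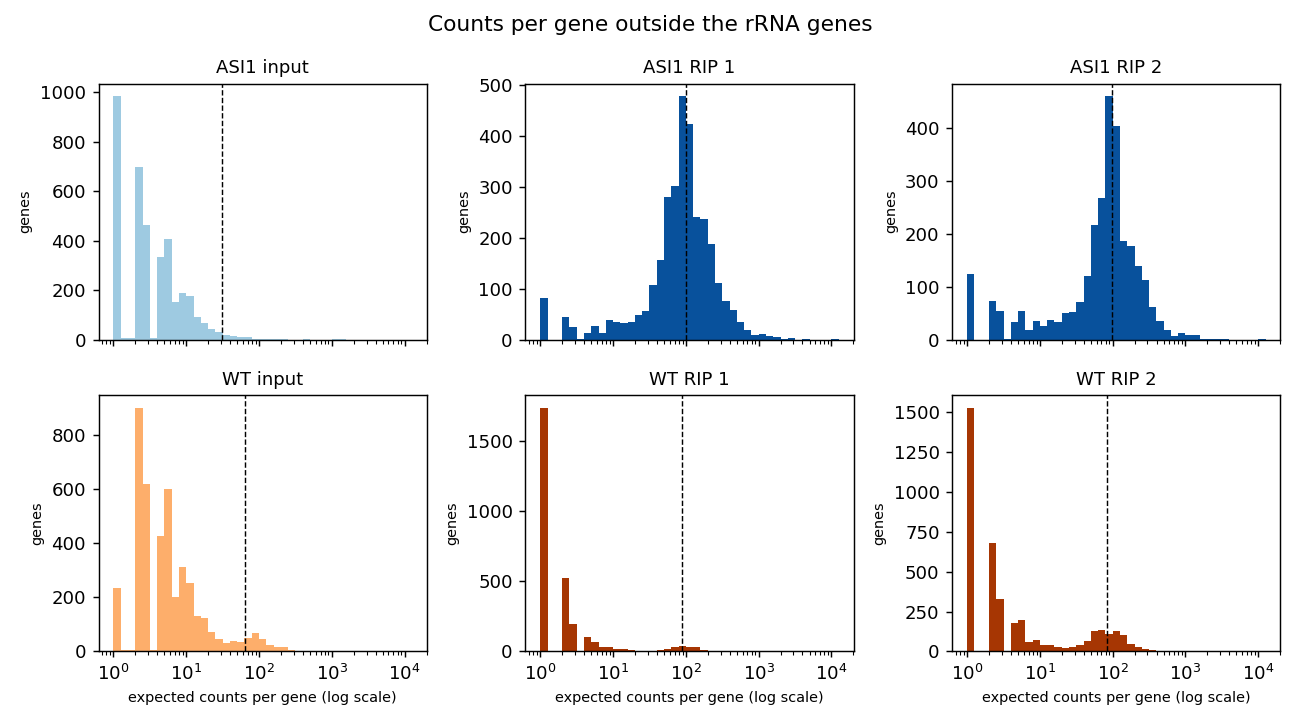
Histograms give the number of genes (y axis) by expected counts per gene (x axis, log scale) outside the rRNA genes, with 1 panel per library; dashed lines mark the median of genes with at least 20 counts and genes below 1 count are not drawn. Covered genes centre on 82.9 to 99.3 counts in the 4 RIP libraries. Most genes of the inputs and of the WT RIP libraries lie below 10 counts.

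Comparing the ASI1 RIP with its input asks which RNAs were recovered with ASI1. The 18S rRNA gene AT3G41768 fell by 4.41 on the log2 scale (SE 0.0968), and no other gene passed the test. The highest non-rRNA level in both ASI1 RIP libraries was that of AT2G15880, a leucine-rich repeat extensin gene, at 23664 and 28019 CPM outside rRNA against 2462 in the input. Other abundant transcripts were EXT3, at 9599 and 8196 CPM outside rRNA against 5863, the pseudogene AT4G16870, at 5516 and 9296 against 3196, AT1G60200, at 6013 and 4373 against 1209, and AT1G15405, at 6509 and 4811 against 50404. The U1 snRNA gene U1.5 stood at 5736 and 6314 CPM outside rRNA against 1079.7, LRX3 at 5358 and 6747 against 777, and the arabinogalactan protein gene AGP9 at 3561 and 4041 against 432. Of these genes all but U1.5 and AT1G15405 were chosen after their values were seen. Extensin genes share repeated sequence, so the division of reads among them is uncertain. The fitted log2 fold of AT2G15880 was 4.48 (SE 1.97), with an adjusted p of 1.00 in edgeR.

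Of the 2312 genes tested, edgeR called 0 higher and 1 lower in the ASI1 RIP, with 3 genes at an unadjusted p under 0.05; DESeq2 called 2 higher and 0 lower, with 11 genes at an unadjusted p under 0.05. The 2 genes DESeq2 called were AT2G25250, at 372 and 90.9 counts in the RIP libraries and 0 in the input, and AT2G35680, at 60.6 and 14.6 against 0. In the WT RIP libraries AT2G25250 had 0 and 190 counts and AT2G35680 115 and 0. As a share of non-rRNA counts the pooled ASI1 RIP libraries lay below the pooled WT RIP libraries for both genes (ratios 0.38 and 0.10). This rests on WT RIP replicate 2 alone for AT2G25250 and on replicate 1 alone for AT2G35680. The call of AT3G41768 ended with DESeq2 (log2 fold -5.20, adjusted p = 0.9996) and with a quasi-likelihood spread free of the abundance trend (adjusted p = 0.9998), so it rests on the spread that edgeR extrapolated to this most abundant gene. The call also ended in edgeR with the ASI1 table fitted alone (log2 fold -5.97, adjusted p = 0.121), so AT3G41768 is not among the genes called lower there. In the authors' deposited table for ASI1 every FDR was 1 and 11 genes had a p under 0.05, 2 with a positive and 9 with a negative log2 fold. The median log2 fold of all genes was 1.12, and 0.09 with scaling to the non-rRNA counts.

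Of the known ASI1 targets RPP7 and IBM1 were measured, at unlike levels in the ASI1 RIP replicates. RPP7 (AT1G58602), a disease resistance gene against downy mildew whose long intron holds a heterochromatic repeat, lies on chromosome 1 (21746354 to 21766048, plus strand), with a longest intron of 7384 bp. It had 674 and 260.0 counts in the ASI1 RIP libraries and 20.6 in the input, or 1503 and 718 CPM outside rRNA against 864. In WT it had 21.6 counts in the input, 0 in RIP replicate 1 and 1.05 in replicate 2. IBM1 (AT3G07610), the histone H3 lysine 9 demethylase gene, lies on chromosome 3 (2425884 to 2433113). It had 0 and 105 counts in the ASI1 RIP libraries against 7.20 in the input, and 0 and 1.05 against 3.09 in WT. As CPM outside rRNA, IBM1 stood at 0 and 291 in the ASI1 RIP libraries against 302 in the input, so neither replicate lay above it. The fitted log2 fold of RPP7 in the ASI1 RIP was 1.34 (SE 3.46, adjusted p = 1.00 in edgeR), and it was -0.37 without ASI1 RIP replicate 1. The RPP7 fold was 0.22 with folds centred on the median, 0.33 with non-rRNA scaling and 0.57 with DESeq2. The other known targets, AT3G05410 and AT1G11270, are not analysed here.

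The large intron of RPP7 (21746500 to 21753883) contains the annotated pseudogene AT1G58561 on the same strand (21748675 to 21753246), which was chosen after its values were seen. AT1G58561 had 1430.1 and 1221 counts in the ASI1 RIP libraries and 27.8 in the ASI1 input, against 0 and 1.05 in the WT RIP libraries and 16.5 in the WT input. As a share of non-rRNA counts the pooled ASI1 RIP libraries lay 415-fold above the pooled WT RIP libraries (95% interval 74.4 to 16392, on 2651 against 1 counts), and the ASI1 input 4.53-fold above the WT input. For RPP7 the RIP ratio was 146 (26.2 to 5779) and the input ratio 2.47 (1.29 to 4.71). For IBM1 the RIP ratio of 16.4 (2.89 to 655) overlapped in its interval with the input ratio of 6.04 (1.38 to 36.2). The overlap of AT1G58561 with the RPP7 intron, and close copies of RPP7 such as AT1G58848 nearby (21791688 to 21797050), make the division of reads among these genes uncertain. AT1G58848, listed in the ASI1 table alone, had 74.8 and 504 CPM outside rRNA in the ASI1 RIP libraries and 1129.9 in the input.

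Transcripts of 4 members of the complex were measured in the ASI1 RIP: ASI1, EDM2, AIPP3 and CPL2. The ASI1 transcript (AT5G11470) had 114 and 201 counts in the ASI1 RIP libraries and 2.54 in the input. EDM2 (AT5G55390), a regulator of RPP7, had 352 and 79.4 counts against 3.09, and 2.08 and 0 in the WT RIP libraries against 7.21 in the WT input. AIPP3 (AT4G11560) had 98.3 and 73.1 counts against 0 in the ASI1 input, and 1.04 and 1.05 in the WT RIP libraries against 8.24 in the WT input. The phosphatase gene CPL2 (AT5G01270) had 100.4 and 0 counts against 4.11, in the ASI1 table alone. The EDM2 log2 fold in the ASI1 RIP was 2.94 (SE 3.55, adjusted p = 1.00 in edgeR), and it was 0.71 without ASI1 RIP replicate 1 and 1.82 with folds centred on the median. AIPP1, AIPP2 and PAIPP2 are not analysed here. Of the complex 2 genes and of the known targets 2 genes were in both tables, too few for a list test.

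**Figure D3:**
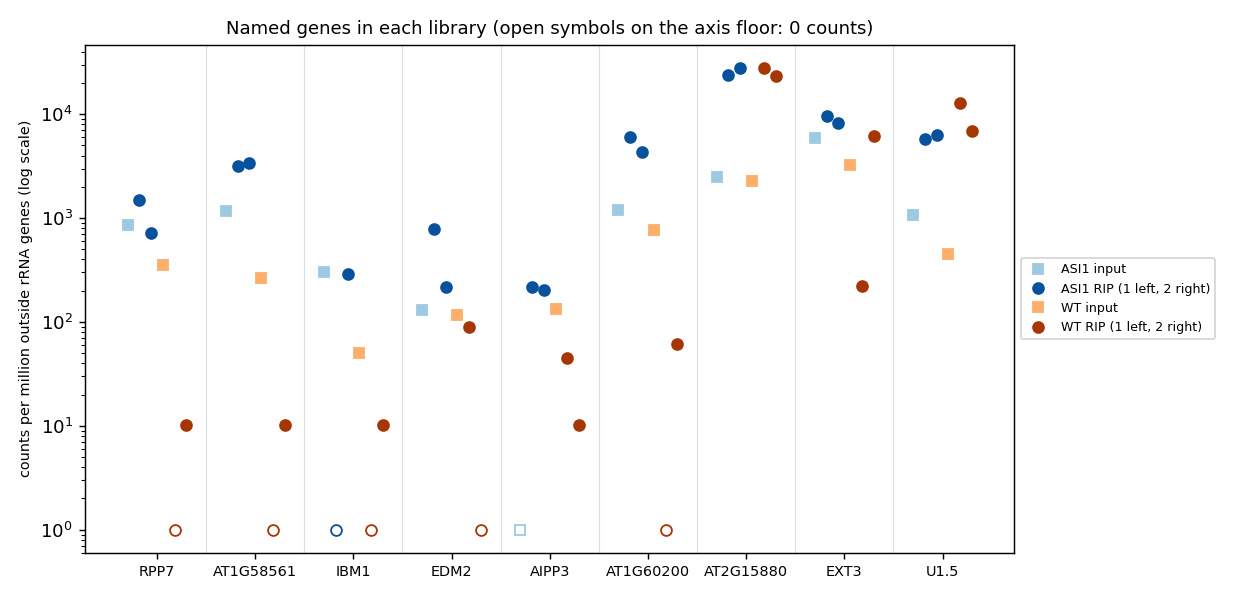
Points give CPM outside rRNA genes (y axis, log scale) in each of the 6 libraries for 9 named genes (x axis); squares are inputs, circles RIP libraries, and open symbols on the floor mark 0 counts. AT1G58561 lay at 3188 and 3372 in the ASI1 RIP libraries and at 0 and 10.1 in the WT RIP libraries, while AT2G15880 lay between 23216 and 28019 in all 4 RIP libraries.

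The WT RIP against its input gives the background of the precipitation. The 18S rRNA gene AT3G41768 fell by 3.52 (log2, SE 0.0944), as the only called gene. The leading transcripts outside rRNA were again AT2G15880, at 27868 and 23216 CPM outside rRNA against 2256 in the input, and U1.5, at 12724 and 6918 against 451. The fitted log2 fold of AT2G15880 in WT was 4.66 (SE 1.99), close to that in ASI1, with an adjusted p of 1.00 in edgeR; without the rRNA genes the folds of 4.73 in WT and 4.37 in ASI1 passed the threshold (adjusted p = 5.6e-07 and 5.3e-06). LRX3 had 204 and 426 counts in the WT RIP libraries against 118 in the input, and EXT3 5.20 and 644 against 199.9.

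In WT edgeR called 0 genes higher and 1 lower of 2312, with 7 genes at an unadjusted p under 0.05; DESeq2 called 0 in either direction, with 62 genes at an unadjusted p under 0.05. The call of AT3G41768 ended with DESeq2 (adjusted p = 0.998) and with a spread free of the abundance trend (adjusted p = 1.00). In the authors' deposited table for WT every FDR was 1 and the smallest p was 0.0560. The median log2 fold of all genes was -0.18, and -1.39 with scaling to the non-rRNA counts.

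The difference between the genotypes asks which RNAs were recovered with ASI1 beyond background. For AT3G41768 the log2 difference was -0.89 (SE 0.137, edgeR adjusted p = 1.8e-07), below the fold minimum of 1. It did not pass with DESeq2 (-1.36, adjusted p = 0.9998) or with a spread free of the abundance trend (adjusted p = 0.9998). Its share was alike in the 4 RIP libraries, at 76.6% to 79.3%, and each genotype has 1 input. Several transcripts abundant in both ASI1 RIP libraries were nearly absent from both WT RIP libraries. These were chosen after their values were seen, among non-rRNA genes listed for both genotypes, which leaves out genes in the ASI1 table alone. There, 44 genes had at least 500 counts in both ASI1 RIP libraries. Of these 44 genes, 7 had under 20 counts in both WT RIP libraries. Besides AT1G58561, they were AT1G60200 and AT4G36980, which encode splicing-related proteins, the aspartyl protease gene AT1G09750, the mitochondrial carrier gene DIC2, pEARLI4 and the pseudogene AT3G43690. AT1G60200 had 2697 and 1583 counts in the ASI1 RIP libraries and 28.8 in the input, against 0 and 6.30 in the WT RIP libraries and 47.4 in the input, a RIP ratio of 112 (95% interval 51.2 to 304). DIC2 had 603 and 794 counts against 1.04 and 0, AT4G36980 755 and 748 against 1.04 and 1.05, and AT3G43690 727 and 819.8 against 1.04 and 2.0995. With the ASI1 table fitted alone, edgeR called AT1G09750 (log2 fold 4.35, adjusted p = 0.00145) and AT2G15880 (2.88, adjusted p = 9.46e-06) higher in the ASI1 RIP than in its input. AT2G15880 does not separate the genotypes, as it was also high in the WT RIP libraries, at 27868 and 23216 CPM outside rRNA against 2256 in the WT input.

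None of these differences passed the test. The log2 difference in enrichment was 6.40 (SE 4.79) for AT1G58561, 6.23 (SE 4.304) for AT1G60200 and 5.65 (SE 5.22) for RPP7, each with an adjusted p of 1.00 in edgeR. Without WT RIP replicate 2 they were 10.555, 12.705 and 9.84, sizes set by a count of 0 in WT RIP replicate 1 for each gene. They were 5.79, 5.42 and 4.40 without ASI1 RIP replicate 1, and 5.30, 5.12 and 4.54 with folds centred on the median. Of 2312 genes edgeR called 0 in either direction at the fold minimum, with 1 gene at an unadjusted p under 0.05, and DESeq2 called 0 with 18. Setting the ASI1 RIP directly against the WT RIP gave 0 edgeR calls, with 18 genes at an unadjusted p under 0.05, and 2 higher and 15 lower DESeq2 calls, with 144 genes. The 2 higher calls by DESeq2 were AT1G58561 (log2 fold 7.40, adjusted p = 0.0285) and AT1G60200 (6.02, adjusted p = 0.0490), against 8.14 and 6.47 in edgeR (adjusted p = 0.949). The 15 lower calls by DESeq2, of which examples were chosen after their values were seen, included ARFA1E (AT3G62290, log2 fold -8.99, adjusted p = 0.000596) and RPS15 (-8.56, adjusted p = 0.00438). The difference of AT3G41768 was -1.14 without WT RIP replicate 1 (adjusted p = 0.185), -1.43 without WT RIP replicate 2 (0.348), and -1.73 and -1.62 without ASI1 RIP replicate 1 and 2.

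The lists of called genes overlapped in AT3G41768 alone. It was the 1 lower gene of each genotype, against 0.000433 shared genes expected among 2312 (Fisher's exact test, two-sided, p = 0.000433). The 2 lists come from 1 fit with a shared spread and are not independent, so this p does not measure chance, and the overlap was 0 without the abundance trend. With 0 genes called higher in either genotype (3 and 7 genes at an unadjusted p under 0.05 in edgeR; 2 and 0 called by DESeq2), the overlap of enriched genes could not be tested.

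Ribosomal protein genes stood apart between the genotypes. The 86 tested genes lay below other genes in the ASI1 RIP (median log2 fold 0.56 against 1.12 over all genes, 54 members above 0, camera adjusted p = 0.0464) and above them in the WT RIP (0.71 against -0.18, 53 above 0, adjusted p = 0.0323). Their ASI1 minus WT difference was lower than that of other genes (median -0.76 against 1.10, 49 of 86 below 0, adjusted p = 0.000736). All 3 calls were lost with an estimated correlation (camera adjusted p = 0.824 with an estimated correlation in each). The estimated correlations in ASI1, WT and the difference were 0.0144, 0.0139 and 0.0129, near the preset 0.01. The fry test, which sets a list against no change and not against other genes, gave adjusted p = 0.897. Over genes at or above the median log CPM the WT call was lost (adjusted p = 0.336, 45 members, median minus that of all genes 0.86). In the fit of all 6 libraries edgeR called no member, over all genes or adjusted over the list alone (0 genes), with 0, 1 and 0 members at an unadjusted edgeR p under 0.05 in the ASI1, WT and difference contrasts. DESeq2 called RPS15 lower in the direct comparison, and without ASI1 RIP replicate 1 edgeR called AT5G16130 lower in the ASI1 RIP (log2 fold -7.88, adjusted p = 0.0352). RPS15 had 12.5 and 0 counts in the ASI1 RIP libraries and 82.1 and 124 in the WT RIP libraries, against 12.3 and 18.5 in the inputs. AT1G67430, a further member, had 101 and 2.09 counts in ASI1 and 1.04 and 5.25 in WT.

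Nuclear photosynthesis genes went the same way without passing the test. The 17 genes had a median log2 fold of -0.25 in ASI1, 0.88 in WT and -1.03 in the difference, 15 of 17 below 0 (camera adjusted p = 0.322, 0.322 and 0.0971; 0.824 in each with an estimated correlation). Set against genes at or above the median log CPM, their WT median lay below that of all genes (0.88 against 1.23). Camera still put them upward there (adjusted p = 0.527). The antenna protein gene LHCB5 had 3109.6 CPM outside rRNA in the ASI1 input and 681 and 49.0 in the RIP libraries, and 2925, 892 and 4207 in WT. LHCA1 had 1900.3, 284 and 185 CPM outside rRNA in ASI1 and 2006, 1115 and 3376 in WT. The 4 rRNA genes had a median log2 fold of -1.98 in ASI1 (camera adjusted p = 0.0528), 0.46 in WT (0.975) and -2.17 in the difference (0.199), and adjusted over the list alone 2, 3 and 1 of them passed.

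Disease resistance genes, of which RPP7 is a member, had a median log2 fold of 1.34 in ASI1, -0.94 in WT and 2.01 in the difference over 17 genes, and 13 of 17 differences lay above 0 (camera adjusted p = 0.619, 0.436 and 0.419). AT5G41740, which encodes a resistance protein of the TIR class, had 341 and 156 counts in the ASI1 RIP libraries and 2.08 and 2.0995 in WT, and RPS2 had 0 and 359 against 153 and 0. Pseudogenes (15 tested) had medians of 1.3995, -0.0039 and 2.05 (adjusted p = 0.445, 0.624 and 0.419). Rapid stress response genes (5 tested) had medians of 1.92, -2.101 and 2.64 (0.437, 0.476 and 0.409), with MYB51 at 215 and 179.6 counts in the ASI1 RIP libraries and 0 and 1.05 in WT. Polyadenylation factors (5 tested) had medians of 1.24, 1.66 and -2.37 (0.551, 0.436 and 0.682), and the poly(A) polymerase gene PAPS4 had 60.6 and 263 counts in the ASI1 RIP libraries against 3.12 and 1.05 in WT. DNA methylation and heterochromatin factors (3 tested) had medians of 0.72, -0.62 and 1.34 (0.471, 0.769 and 0.769), and AGO4 had 0 and 179.6 counts against 1.04 and 2.0995.

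Among the remaining lists no camera test passed. Reference genes (9 tested) had medians of 1.14, 0.65 and -0.71 in ASI1, WT and the difference (adjusted p = 0.624, 0.471 and 0.471), with UBQ10 at 1047 and 953 counts in the ASI1 RIP libraries, 15.6 and 125 in the WT RIP libraries, and 21.8 and 133 in the inputs. Pentatricopeptide genes (3 tested) had medians of 0.93, -0.94 and 1.85 (0.624, 0.624 and 0.930). The lncRNA genes (5 tested) had medians of 1.69, 0.85 and -2.31 (0.769, 0.409 and 0.471) and other ncRNA genes (5 tested) 2.40, -1.70 and 3.08 (0.471, 0.471 and 0.409). GUT15, an unstable noncoding transcript, had 294 and 285 counts in the ASI1 RIP libraries and 0 and 1.05 in WT. The direction of the camera test was opposite to that of the median against all genes for pseudogenes in WT, reference genes in ASI1 and DNA methylation factors in the difference. In the lists other than rRNA the edgeR fit of all 6 libraries called 0 members, over all genes or adjusted over the list alone; at an unadjusted edgeR p under 0.05 lay 1 polyadenylation factor in WT and 0 others besides ribosomal protein genes. In the direct comparison DESeq2 called the reference gene TUB2 (AT5G62690) lower (-7.64, adjusted p = 0.0358) and, besides RPS15, the pseudogene AT1G58561. With the ASI1 table fitted alone, edgeR called LHCB5 (-3.57, adjusted p = 0.00619), CAB1 (-2.13, adjusted p = 0.00619) and the noncoding AT1G15405 (-3.65, adjusted p = 3.89e-15) lower in the ASI1 RIP.

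Lists with fewer than 3 tested genes are given as counts or CPM. The heat shock cognate gene HSC70-1 had 1666 and 2423 CPM outside rRNA in the ASI1 RIP libraries against 4319 in the input, and 4726 and 4745 against 4964 in WT. Of the root markers, PYK10 had 454 and 170.2 CPM outside rRNA in the ASI1 RIP libraries against 1900.3 in the input, and 312 and 193 against 685 in WT, and SCR had 230.0 and 71.0 counts in the ASI1 RIP libraries. The phloem gene SUC2 had 336 and 86.7 counts in ASI1 and 2.08 and 121 in WT, and the guard cell gene FAMA 0 and 81.5 against 0 and 1.05. Of the 2 histone genes in both tables, HTB9 had 95.6 and 257 CPM outside rRNA in the ASI1 RIP libraries against 0 in the input, and 44.6 and 11.1 against 33.4 in WT. AT4G40040 had 133 and 2.88 CPM outside rRNA against 216 in ASI1, and 44.6 and 1054 against 1119.8 in WT. The transposase gene AT3G19120 had 251 and 60.6 counts in ASI1, and the snoRNA gene U3D 86.2 and 314 CPM outside rRNA against 1018 in the ASI1 input. U1.5 was the 1 snRNA gene in both tables. Of 7 seed storage genes 1 was listed, in WT, where the list made up 0.0943% of the non-rRNA counts of RIP replicate 2.

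Because heterochromatin inside introns marks the known ASI1 targets, folds were compared with gene structure. Across 2281 protein-coding genes the log2 fold fell with exon number in ASI1 (Spearman's rho -0.167, adjusted p = 3e-05, permutation p = 1e-05, the smallest the permutations can give) and in WT (-0.0897, permutation adjusted p = 6.75e-05). It fell with gene length in ASI1 (-0.104) and WT (-0.180), each with a permutation adjusted p of 3e-05, and slightly with the longest intron (-0.0493 and -0.0588, permutation adjusted p = 0.0233 and 0.00750), though neither passed over the 1131 genes at or above the median log CPM (0.0785 and 0.163). The ASI1 minus WT difference rose with gene length (0.0839, permutation adjusted p = 0.000108) and showed no relation past the threshold with exon number (-0.0238, 0.286) or longest intron (0.0173, 0.410). The 86 genes with an intron of at least 1000 bp had a median log2 fold of 1.08 in ASI1, -0.61 in WT and 1.68 in the difference (camera adjusted p = 0.655, 0.469 and 0.469; in ASI1 camera put them upward although their median lay below that of all genes). The 218 intronless genes lay above other genes in ASI1 (1.52 against 1.12, 183 of 218 above 0, camera adjusted p = 0.00761), a call lost with an estimated correlation (adjusted p = 0.877 with an estimated correlation). The call was also lost over genes at or above the median log CPM (119 intronless genes, camera adjusted p = 0.178). In WT and the difference the intronless genes had medians of -0.01 and 1.52 (adjusted p = 0.731 and 0.133). Genes are not independent replicates in these relations.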

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

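The tests of the pile-up of counts, of the genes low in the WT RIP libraries and of transcript length were chosen only after the results were seen; the test of ribosomal protein genes at higher counts was planned, but its result was known when its reading was set.

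The change of the 18S rRNA gene AT3G41768 differed between the genotypes by a test of the difference itself, at -0.89 on the log2 scale (edgeR adjusted p = 1.8e-07). This was lost with DESeq2 (-1.36, adjusted p = 0.9998), with a spread free of the abundance trend (0.9998) and without WT RIP replicate 1 (-1.14, 0.185) or 2 (-1.43, 0.348).

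For 17 named genes both RIP libraries of 1 genotype lay above their input and both of the other genotype below it. These differences were not tested in this form, and the edgeR test of the difference called none of them. AT1G58561, AT1G60200, AT1G09750, AT4G36980, DIC2 and pEARLI4 were chosen for high ASI1 and low WT RIP counts, which favours this pattern. Like U1-70K, ATU2AF65A and RS41, they were chosen after their values were seen. Of 2319 genes outside rRNA, 279 (12.03%) lay higher in ASI1 and lower in WT in this way and 66 (2.85%) the reverse. A random order of the libraries gives 11.1% for each. That is not the share by chance here, since WT RIP levels mostly lay below their input (median log2 fold -1.39 with non-rRNA scaling). In the ASI1 RIP libraries AT1G58561 averaged 3280.0 CPM outside rRNA (1166 in the input), AT1G60200 5193, AT1G09750 3638, AT4G36980 1874, DIC2 1768 and pEARLI4 1932, and each was measured under its input in WT. The same held for EDM2 at 502, AIPP3 at 210.5, MYB51 at 488, UBQ10 at 2482, the pseudogene AT5G14840 at 688, the noncoding RNAs GUT15 at 721 and AT4G08035 at 846, and the splicing factor genes U1-70K at 1221, ATU2AF65A at 1138 and RS41 at 899.6. All of these but UBQ10 had under 20 counts in both WT RIP libraries, and a count of 0 in replicate 1 allows up to 129 CPM outside rRNA. For genes with a WT input of 167 CPM outside rRNA or less, the counts are too few to place the WT RIP libraries under the input. These were EDM2, AIPP3, MYB51, AT5G14840, GUT15, DIC2, pEARLI4 and RS41. The floor covers counting error only, so it does not settle the remaining genes either. RPS15 went the other way, with an ASI1 RIP mean of 14.0 CPM outside rRNA against 518 in the ASI1 input and a WT RIP mean of 2359 against 301.

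Covered genes carried about the same count in every RIP library. A depth that sets this count is argued against: the medians of covered genes spanned 1.198-fold over the 4 RIP libraries while their non-rRNA totals spanned 19.2-fold. A property of the ASI1 line as the whole cause is argued against by WT, where the lowest ratio of genes at 80 to 110 counts to genes at 10 to 40 was 0.794, above the highest input at 0.151. The ASI1 RIP libraries lay higher still, at 2.11 and 2.49, so a part due to the line stays open. Few starting molecules, each amplified to many reads, may account for it: 46.5% of the genes covered in either ASI1 RIP library (1783 of 3837) had 0 counts in the other, and 32.1% in WT, shares that leave out genes at 0 in 2 of the 3 libraries of a genotype. If so, a count near the median could stand for a lone molecule, and the fold of such a gene carries the error of few draws. However, 2578 and 2731 genes of the WT RIP libraries held 1 to 5 counts, against 164 and 288 in the ASI1 RIP libraries. A count per molecule near the median does not account for those genes.

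Among genes listed for both genotypes, AT1G58561, inside the RPP7 intron, and 6 others had at least 500 counts in both ASI1 RIP libraries. These 7 genes had under 20 counts in both WT RIP libraries. A higher level of these RNAs in the ASI1 seedlings cannot be weighed with these genes, since they were chosen for high ASI1 and low WT RIP counts. Pooled over the 7 genes the ASI1 input lay 2.11-fold above the WT input (95% interval 1.61 to 2.75). Single genes ranged from 0.28 (AT1G09750) to 6.47 (AT3G43690, 1.06 to 68.0), with AT1G58561 at 4.53 (2.37 to 8.96). The lowest RIP ratio, with WT set to no less than 3 counts, was 15.8, a value that the choice keeps high. Fewer molecules in the WT RIP libraries cannot be told apart from binding. At an assumed 85.1 counts per molecule 1.37 of the 44 genes would be expected without a WT molecule (7 or more in a share of 0.00022 of draws). These draws cannot decide it, since the number of counts per molecule is not known. In addition, each of the 44 genes needed a WT RIP count above 0 to be listed, so none was without WT reads. Binding of these RNAs by tagged ASI1 may contribute and stays open, untested.

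Ribosomal protein genes were lower than other genes in the ASI1 minus WT difference. Short transcripts as the whole cause are argued against: 0.0600% of 10000 random lists matched on transcript length had a median at or below theirs of -0.76 (random lists 0.44). Low counts cannot be told apart from it: over genes at or above the median log CPM their median minus that of all genes was -1.59, against -1.87 over all tested genes (camera adjusted p = 0.0117; adjusted p = 0.808 with an estimated correlation), but the 45 members kept still had a median of 6 counts in the ASI1 input and 4 in WT RIP replicate 1. Chance stays open. The call was lost with an estimated correlation (camera adjusted p = 0.824), but hardly any list could pass that test with 2 residual degrees of freedom. The loss therefore does not decide for or against chance. The estimated correlation, 0.0129, lay near the preset 0.01, so the loss cannot be put down to co-varying genes. A difference between the genotypes in ribosome-bound RNA is a possible explanation that was not tested.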

How the results depend on the processing

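The direct ASI1 RIP against WT RIP comparison and the settings marked added were chosen only after the results were seen. Of 359 values recomputed under alternatives, 295 were classed as the same, 36 as moved, 21 as weaker, 5 as stronger and 2 as reversed. In the first class folds and lists kept their side of the threshold, and counts of genes stayed equal or close. Intron classes that passed no threshold were put there even when their direction turned. Many counts of 0 could hardly change, given the low power of the fit. Where no cause is named, the cause was not tested. The number of genes higher in the ASI1 RIP was 0, and 2 with DESeq2, 1 without the rRNA genes (added) and 2 with each table fitted alone (added). The number lower was 1 and ranged from 1 to 10 when a RIP replicate was left out (10 without ASI1 RIP replicate 1, 2 without WT RIP replicate 1; a lone sample is then assumed to vary like the other groups). It was 0 with DESeq2, with the authors' deposited p-values adjusted anew, with no abundance trend (added) and without the rRNA genes (added, as the called gene is then absent), 2 with non-rRNA scaling and 11 with each table alone (both added). In WT the number higher was 0 and became 1 without the rRNA genes, and the number lower was 1 and became 0 with DESeq2, without the rRNA genes, with no trend, with the table alone and with the authors' deposited p-values. Lower genes in the ASI1 minus WT difference were 0, and 0 to 1 leaving out a replicate, 1 with centred folds and 1 with no fold minimum. In the direct comparison, 0 became 2 higher and 15 lower with DESeq2, and the lower count was 0 to 3 leaving out a replicate, 1 with centred folds and 1 with no fold minimum. The shared lower gene, 1, became 0 with no trend. The RPP7 fold in the ASI1 RIP was 1.34; it ranged from -0.37 (without ASI1 RIP replicate 1) to 1.33 leaving out a replicate, and reversed to -0.16 with the table alone. Lists past the threshold were 1 in each contrast; at or above the median log CPM they were 2 in ASI1 and 0 in WT, and with an estimated correlation or fry (against no change) they were 0 in all 3. The relation to the longest intron no longer passed at or above the median log CPM, with rho -0.0575 in ASI1 (permutation adjusted p = 0.0785) and -0.0455 in WT (0.163), where fewer genes were tested.

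Whether replicate numbers pair the libraries could not be settled. Same-numbered RIP libraries of the genotypes had deviations that correlated at -0.000576 (Pearson) across 2319 genes. With replicates as far apart as here (dispersion 2.19), a shared batch could go unseen. With the replicate block edgeR called 0 higher and 1 lower in ASI1, 0 and 1 in WT, and 0 and 0 in the difference.

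A count of 0 allows up to 129 CPM outside rRNA in WT RIP replicate 1 and up to 126 in the ASI1 input. In simulated counts at the dispersion of these libraries the fit called 0 of 100 genes raised 64-fold in the ASI1 RIP, so a count of 0 calls does not show that no RNA was enriched.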

Other observations

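The tests of the splicing factor, extensin and pseudogene lists were all chosen only after the results were seen.

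Transcripts of splicing factors were set against other genes in the ASI1 minus WT difference. Of 20 tested genes 19 had a difference above 0, with a median of 3.21 against 1.10 over all genes (camera adjusted p = 0.00145; adjusted p = 0.238 with an estimated correlation). They lay above other genes in the ASI1 RIP (median 2.03, adjusted p = 0.0422) and below them in the WT RIP (median -1.94, adjusted p = 0.0190), both with adjusted p = 0.238 with an estimated correlation. U1-70K, a protein of the U1 particle, had 412 and 551 counts in the ASI1 RIP libraries and 0 and 5.25 in the WT RIP libraries, although its input held 16.5 counts in ASI1 and 193 in WT. RS41, which encodes an SR splicing protein, had 469 and 273 counts against 0 and 1.05. The hypothesis that ASI1 recovers such transcripts may hold, but edgeR called no member. All 3 calls were also lost with an estimated correlation, a test that hardly any list could pass with 2 residual degrees of freedom. The estimated correlations lay below 0 (-0.0108, -0.0187 and -0.0179), so the loss cannot be put down to co-varying genes. DESeq2 called AT1G60200 higher in the direct comparison and AT2G25250 higher in the ASI1 RIP than in its input. As a pooled share AT2G25250 lay lower in the ASI1 RIP than in the WT RIP (ratio 0.38, 95% interval 0.32 to 0.45, counting error only). That direction rests on WT RIP replicate 2 alone, as the WT RIP libraries held 0 and 190 counts.

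Extensin and proline-rich transcripts were set against other genes in the RIP of both genotypes. The 43 tested extensin and proline-rich genes had a median log2 fold of 1.99 in ASI1 against 1.12 over all genes (37 of 43 above 0, camera adjusted p = 0.00145) and 1.88 in WT against -0.18 (27 of 43 above 0, adjusted p = 0.0810). The hypothesis that these RNAs are recovered without ASI1 rests on the WT RIP, where the list did not pass the threshold. With an estimated correlation neither genotype passed (adjusted p = 0.238 and 0.434 with an estimated correlation). Their ASI1 minus WT difference had a median of 0.58 against 1.10, while camera put it upward with an adjusted p of 0.386.

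Pseudogenes were often covered in both ASI1 RIP libraries. Of 56 listed pseudogenes 27 (48.2%) reached 20 counts in both, against 1409 of 3960 other genes (35.6%; Fisher's exact test, two-sided, p = 0.0668). The hypothesis of a higher share did not pass the threshold. The pseudogene AT4G16870, beside the disease resistance gene RPP4 (AT4G16860) on chromosome 4, had 2474 and 3366 counts in the ASI1 RIP libraries against 76.1 in the input, and 0 and 99.7 in WT against 34.0. RPP4 had 427 and 53.2 counts in the ASI1 RIP libraries against 15.3 in the input. As CPM outside rRNA these were 951 and 147 against 641, so the replicates lay on either side of the input.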
